A study of Arabidopsis thaliana with 2 samples.

How the data were processed

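Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to whole seedlings of Arabidopsis thaliana, ecotype Col-0, collected 10 days after sowing. Per the labels' protocols, the plants grew at 22 °C under a photoperiod of 16 h without treatment. One sample came from plants that express IBH1, an atypical basic helix-loop-helix (bHLH) protein, fused to green fluorescent protein (GFP) from the strong 35S promoter. The other came from plants that express GFP alone from that promoter, and both were precipitated with an antibody against GFP. Per the labels' protocols, DNA from 3 independent ChIP experiments was pooled before a library was made and amplified with 18 PCR cycles, so each group is a single library and no spread between replicates can be had. The labels differ in places: the title of the tagged sample names IBL1, a relative of IBH1, while its line, its protocol and the series' design name IBH1. The line of the control is given as GFP-expressing, while the library protocol names the wild type Col-0. Groups were taken from the line.

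The authors deposited a list of peaks and a list of their summits for the whole series. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie and MACS were used, with the genome build TAIR9. Their settings, and whether the control library served as the background in peak calling, are not given in the sources used here. Neither list names a sample. They are read here as the IBH1-GFP peaks because the series' design is about occupancy by IBH1. The deposited score of each peak is the caller's own. MACS writes 10 times the −log10 of its p-value there, and the lowest deposited score was 50.01. The deposited signal at each summit is a whole number of stacked fragments. Both are the authors' values for one list from pooled DNA, so they rank peaks within that list only. Peaks weaker than the authors' threshold are not listed. Read totals of the libraries are not given in the sources used here, so the depth is unknown. The intervals below cover counting error only.

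Genes were named from a RefSeq gene table of the assembly TAIR10.1, which gives gene bounds but no strand and no exons. The nuclear chromosome sequences were carried over from TAIR9 to TAIR10, and this was tested on the data by shifting all summits in steps of 100 bp up to 5000 bp either way. The share of summits in protein-coding genes was highest within 200 bp of no shift on each of the 5 chromosomes. Gene bounds of that table are used only to say which genes hold or neighbour a peak, and every coordinate printed is the authors' TAIR9 coordinate, counted from 1. The table held 27444 nuclear protein-coding genes. The mitochondrial peak was not placed against genes.

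Without genome sequence, the planned tests of the G-box, of all hexamers and of the G-box against the score were not run. Without strand, the planned share of summits upstream of genes was replaced by the share inside protein-coding genes. A gene was counted as bound when a summit lay inside it or within 1000 bp of either end, in place of the planned window of 2000 bp upstream to the gene's end. "Bound" means only this. Positions were compared with 10000 random placements of the summits on their own chromosome (two-sided permutation p). Reads that fit several places are often lost in repeats, and random placement does not model that. Windows of 500000 bp with under 60 protein-coding genes are called gene-poor here, and 36 of 240 windows were.

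Gene lists were fixed before the data were examined. They cover the bHLH network around IBH1, brassinosteroid synthesis and signalling, light signalling, the circadian clock, gibberellin, Aux/IAA, ARF, SAUR, expansin, XTH, cellulose synthase, aquaporin, PIN, JAZ, ERF and DREB, and WRKY genes. Light-harvesting and RBCS, ribosomal protein and heat shock genes were added as lists of abundant or inducible transcripts. Of 123 gene codes in the hand-written lists, 3 were dropped because their symbol did not match the table. These were PRE2 and PRE4 of the bHLH network and PIF8 of the light list, which were not examined. Families matched by symbol or alias can hold unrelated genes. Each list was compared with 10000 random lists of the same size matched on gene length in 20 bins (two-sided permutation p), with Benjamini-Hochberg adjustment over the 19 lists at 0.05. Genes and peaks of a single list are not replicates, so every p describes this peak list and not the spread between ChIP experiments.

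The genes named in the text follow a rule fixed before the data were examined: each bound member of the bHLH network and brassinosteroid lists, up to 4 bound members with the highest score of each other list, and the nearest protein-coding gene (by bounds, for want of strand) of the 15 nuclear peaks with the highest score (the rule aimed at about 30 genes, and the text names more). The remaining bound members of the light list, unbound members given as examples, and RPS2, SIP1 and BRX, which a symbol or alias had caught, were named after their values were seen. The dropped genes are named as well, without values. Alternatives were a score of at least 100, the peaks at or above the median score, the midpoint in place of the summit, other windows around genes, other random models, peaks within 500 bp merged, and peaks in gene-poor windows left out.

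The tests were tested on simulated data. For the 2944 nuclear summits, 4 of 100 simulations without an effect passed 0.05. When 70% of the summits were placed inside genes, 100 of 100 passed and 69.9% was recovered. That share was planted and counted with the same gene bounds, so it checks the counting and not the power for smaller excesses. For the lists over 27444 genes, 0 of 100 simulations without an effect called any list. These simulations drew each gene independently at the rate of its length bin. They left out the clustering of bound genes along the chromosomes, so false calls that clustering may cause were not checked. A light list bound at 3 times its expected share was called in 60 of 100. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.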

Results

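Genome-wide occupancy of IBH1 was measured by ChIP-seq in 10-day-old Arabidopsis seedlings. IBH1 is a helix-loop-helix protein that represses cell elongation in the brassinosteroid pathway. The design holds 1 library of IBH1-GFP plants and 1 library of GFP plants as the control, without replicates. The deposited list held 2945 peaks, 2944 on the 5 nuclear chromosomes and 1 on the mitochondrial genome. Peaks had a median width of 885 bp (quartiles 723 and 1119 bp). The median score was 72.8 (quartiles 58.9 and 99.5), and 729 peaks scored 100 or more. Summits were 14 to 100 fragments high, with a median of 27. Across peaks, which are not independent replicates, score and height had a Pearson r of 0.50 and a Spearman rho of 0.46.

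The first question was whether the tagged gene itself appears in the list. The peak with the highest score and the tallest summit of the whole list lay over IBH1 (AT2G43060). It spanned chromosome 2, 17908801 to 17909883 (TAIR9), with a score of 1045.71 and a height of 100. The summit at 17909502 was inside the gene, and 877 of the 1083 bp of the peak overlapped it. The score was 1.96 times that of the next peak, which scored 534.1. In height it stood out less, as the next tallest summit was 92 fragments high. No summit lay within 1000 bp of IBL1 (AT4G30410), the gene named in the sample's title. Exons and introns were not annotated here, and without a second library the height has no replicate error.

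**Figure D1:**
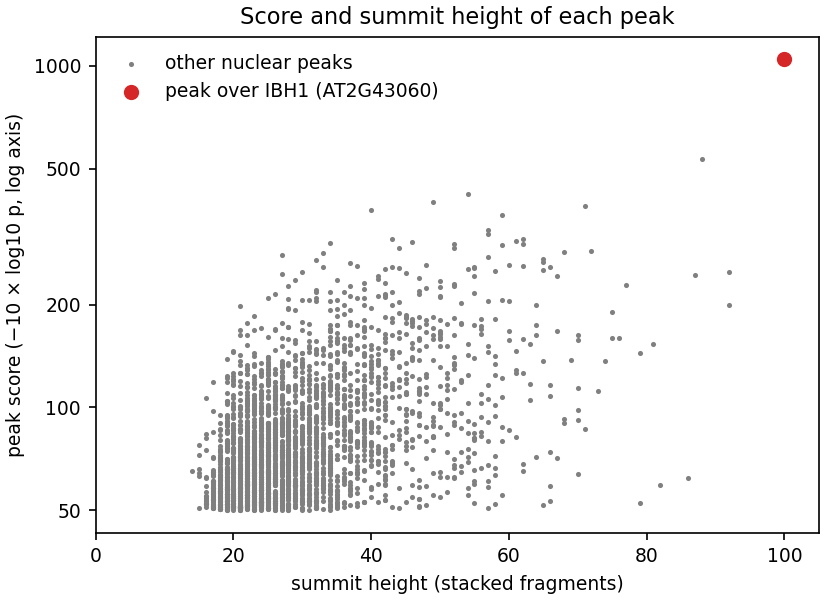
Score of each nuclear peak (log axis, 10 times the −log10 p of the caller) against the height of its summit in stacked fragments. The peak over IBH1, with a score of 1045.71 and a height of 100, stands above the next score of 534.1.

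The other peaks among the 15 with the highest scores lay beside genes of mixed function. The second, on chromosome 2 from 6017828 to 6018909, had its summit 260 bp from AGL44 (AT2G14210), a MADS-box regulator of the root's response to nitrate. The third, on chromosome 4 from 2717424 to 2720568, scored 421.36 and had its summit 41 bp from the polyubiquitin gene UBQ10 (AT4G05320). Summits inside genes followed at BTI2 (AT4G11220, score 400.82), QRT3 (AT4G20050, 388.02), a polygalacturonase of pollen separation, and PHI-1 (AT1G35140, 378.88). GSL1 (AT4G04970), a callose synthase gene, had a summit 201 bp away with a score of 367.11. A summit with a score of 330.73 lay in MYC2 (AT1G32640), the bHLH factor of jasmonate signalling, where its bounds overlap those of AT1G32630. GSTF10 (AT2G30870), a glutathione transferase gene, held a summit with a score of 305.53, and a summit 39 bp from GRF1 (AT4G09000), a 14-3-3 protein gene, scored 302.46. The genes AT3G44190, AT5G45590, AT3G43670 and AT1G35220 held summits scoring 307.6 to 321.52. The last of the 15 peaks, with a score of 301.95, was 2247 bp from its nearest protein-coding gene, AT3G29255. In all, 10 of the 15 summits lay inside a protein-coding gene.

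The next comparison placed all summits against genes. Summits lay inside protein-coding genes more often than random positions did: 1987 of 2944 summits, or 67.5%, against 53.9% under random placement (95% of draws between 52.1% and 55.7%). The permutation p was 0.0002, the smallest that 10000 draws can give, and 0.00025 after adjustment over the 5 classes tested. Summits outside genes but within 1000 bp of a protein-coding gene made up 19.3%, against 19.0% (adjusted p = 0.67, permutation). Summits farther from any protein-coding gene and outside any other annotated gene made up 5.77%, against 17.0%. Those in another annotated gene only, such as pseudogenes and RNA genes, made up 7.40%, against 10.1%. Both shares were lower than under random placement (adjusted p = 0.00025 each, permutation). On each chromosome the share inside genes was highest within 200 bp of no shift, between 65.2% and 70.3%, and with shifts of 2000 bp or more it stayed at or below 64.2%. The share was 67.5% against 56.9% when each summit was placed at random within 20 kb of itself. Without strand, the start of a gene could not be told from its end.

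**Figure D2:**
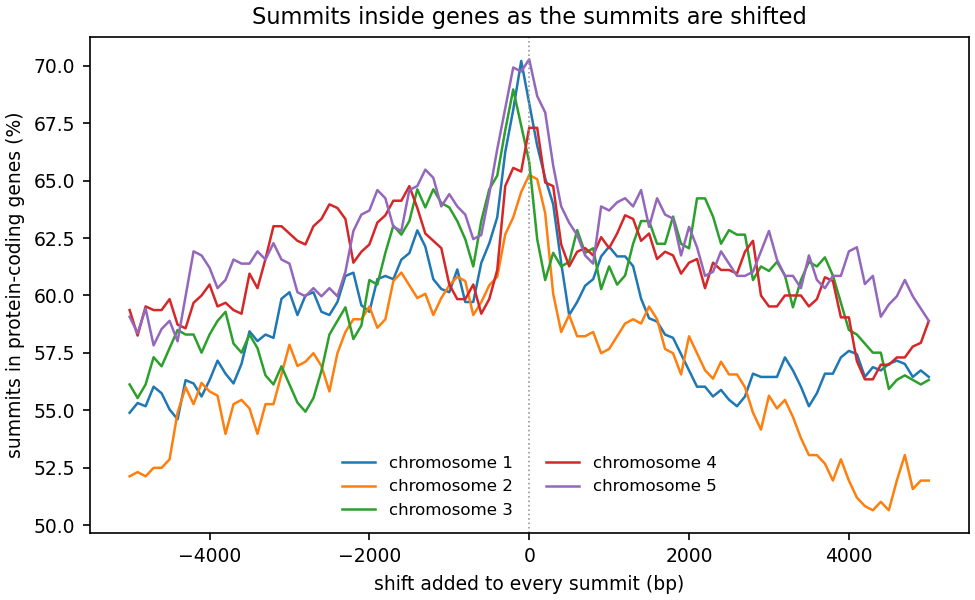
Percent of summits inside protein-coding genes on each nuclear chromosome when every summit is shifted by the distance on the x axis (bp). All 5 lines are highest within 200 bp of no shift, at 65.2% to 70.3%.

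Gene-poor windows, which lie around the centromeres and in a few other places, held few peaks for their length. They held 173 summits, or 5.88%, against 15.2% under random placement (p = 0.0002, permutation, the smallest possible). Per gene there was no such deficit overall: 141 of the 953 protein-coding genes there (14.8%, exact 95% interval 12.6% to 17.2%) had a summit inside or within 1000 bp, against 12.7% of all genes. Chromosome 3 differed, with 6 of 190 genes there (3.16%), below the rest of that chromosome. Chromosome 4 had the most peaks for its length, 33.9 per Mb (95% Poisson interval 31.3 to 36.7), and chromosome 5 the fewest, 20.8 per Mb (19.1 to 22.6). Median scores ranged from 70.4 on chromosome 5 to 76.7 on chromosome 4. Reads from repeats are often discarded at alignment, which the random placement does not model.

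**Figure D3:**
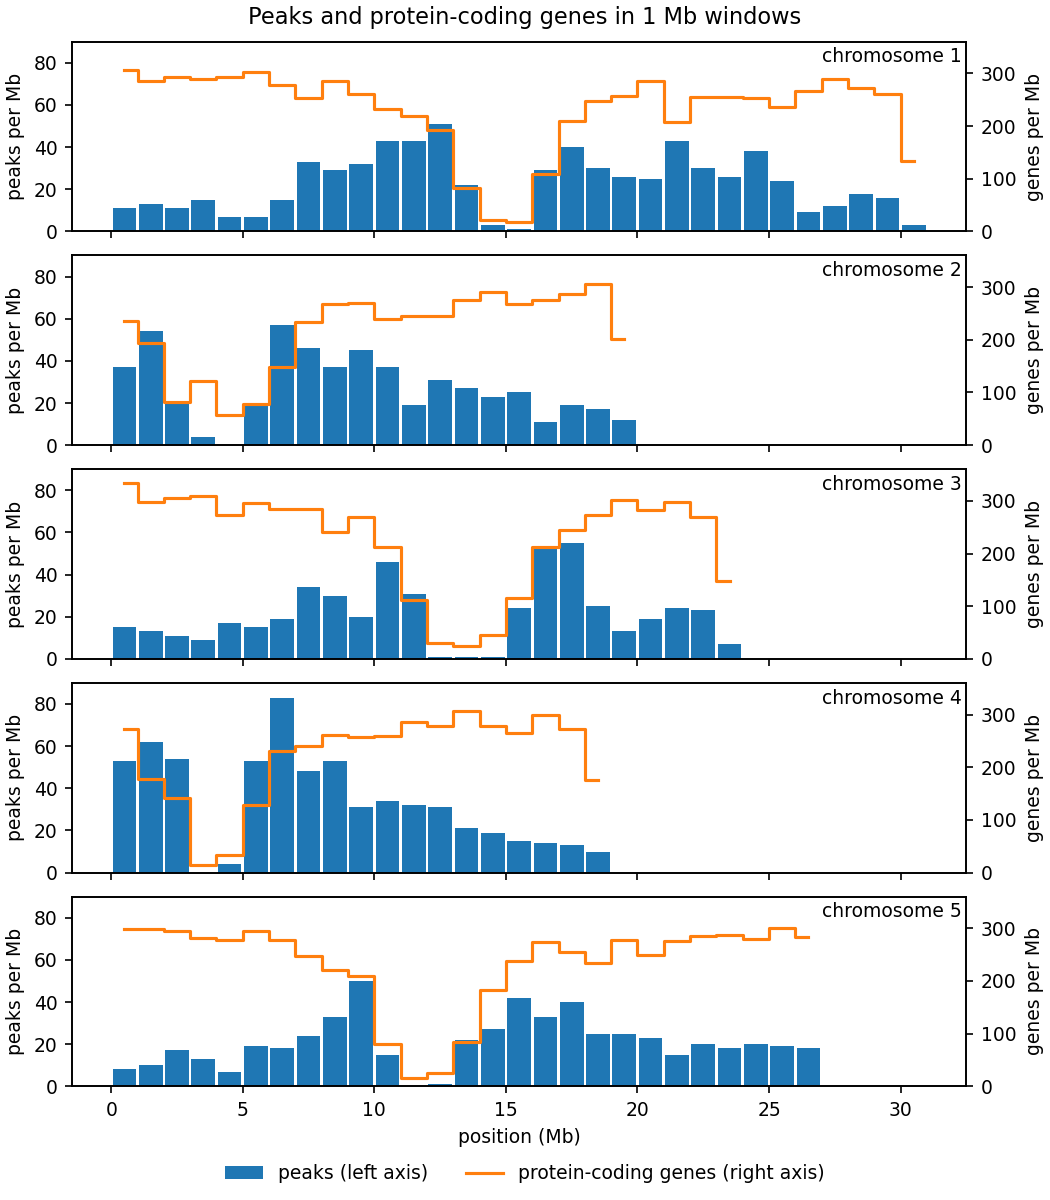
Number of peaks (bars, left axis) and of protein-coding genes (line, right axis) in 1 Mb windows along the 5 nuclear chromosomes. Peak counts fall to 0 to 4 in several windows with the fewest genes and are highest in windows beside them, up to 83 on chromosome 4.

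In all, 3499 of 27444 protein-coding genes (12.7%) had a summit inside or within 1000 bp. Of these, 1934 held a summit inside their bounds. A single gene was within reach of 1598 peaks, 2 or more genes of 1065 peaks, and none of 281 peaks. A summit between neighbours therefore counts for both.

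The bHLH network, in which IBH1 acts against growth-promoting bHLH proteins, was not bound more often than other genes. Summits were found at 3 of 26 members, against 3.31 in random lists matched on gene length (adjusted p = 1, permutation). Over the alternatives the ratio ranged from 0.69 to 1.28. The count includes IBH1, whose peak may come from DNA of the transgene. Besides IBH1 itself the bound members were BPE (AT1G59640, listed as BPEp, score 77.4), which limits petal size, and PAR2 (AT3G58850, 58.3), an atypical bHLH repressor of shade responses. No summit lay near the unbound members HBI1, BEE1, BEE2, BEE3, CIL1, PRE1, PRE3, PRE5 and PRE6. PRE2 and PRE4 had been dropped from the list and were not examined.

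Of the brassinosteroid genes, 6 of 32 were bound, against 4.79 expected (adjusted p = 1, permutation). For summits inside genes alone the count was 2, against 2.79 expected. BAS1 (AT2G26710), which inactivates brassinosteroids, held a summit with a score of 109.7 at chromosome 2, 11382128 to 11383539. BIL1 (AT2G30980, listed as SKdZeta), a kinase related to BIN2, held a summit with a score of 86.9. Summits lay outside but near the BZR1 homologues BEH3 (AT4G18890, 330 bp, score 69.5) and BEH4 (AT1G78700, 292 bp, 53.5) and the receptor gene BRL1 (AT1G55610, 235 bp, 53.3). For BIN2 (AT4G18710), the GSK3-like kinase of the pathway, the summit (score 151.1) was 840 bp away. It lay 95 bp from RPL16B and within 200 bp of a tRNA gene. No summit lay near the receptor BRI1, the transcription factors BZR1 and BES1, or the biosynthetic genes DWF4, CPD and DET2.

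Light signalling was the list bound more often than random lists: 11 of 28 genes (39.3%, exact 95% interval 21.5% to 59.4%), against 3.98 expected, a ratio of 2.76 (adjusted p = 0.046, permutation). Among them were 4 of the 5 phytochromes, the red light receptors: PHYB (AT2G18790), PHYC (AT5G35840), PHYD (AT4G16250) and PHYE (AT4G18130). PHYA had no summit, and that of PHYD was 128 bp outside the gene and nearer to AT4G16260. COP1 (AT2G32950), a ubiquitin ligase that represses light responses, had the highest score of the list, 133.3, with its summit 16 bp outside the gene at chromosome 2, 13977865. Its partner SPA1 (AT2G46340, 57.0), the blue light receptor CRY1 (AT4G08920, 51.0), the transcription factors FAR1 (AT4G15090, 79.3) and FHY3 (AT3G22170, 50.3), PIF5 (AT3G59060, listed as PIL6, 68.9) and the shade-induced ATHB2 (AT4G16780, listed as HB-2, 60.3) were also bound. The unbound members included PIF1, PIF3, PIF4, PIF6, PIF7, PIL1, HY5, HYH and CRY2. The phytochrome peaks scored 51.2 to 62.0, close to the lowest score of the list, although the summit near PHYB was 86 fragments high. The result rests on weak peaks: with scores of 100 or more only COP1 was left, against 1.04 expected, and among the peaks at or above the median score 2 genes against 2.05 (adjusted p = 1 for both, permutation). It also missed the threshold for summits inside genes alone (7 genes, ratio 3.08, adjusted p = 0.12, permutation) and without chromosome 4 (6 of 23 genes, ratio 1.95, adjusted p = 0.72, permutation).

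The other lists did not pass the threshold. For hormone and clock genes, 5 of 18 gibberellin genes were bound (ratio 2.03, adjusted p = 0.57, permutation), among them the DELLA repressors RGL3 (AT5G17490, score 121.7), RGL1 (AT1G66350, 75.5) and RGL2 (AT3G03450, 63.6). The DELLA genes GAI and RGA, also in that list, were not bound. In the clock list 4 of 16 were bound (ratio 1.70, adjusted p = 0.77, permutation). These were LUX (AT3G46640, listed as PCL1, score 144.3), CHE (AT5G08330, listed as TCP11, 67.8), GI (AT1G22770, 66.4) and CCA1 (AT2G46830, 51.7). The summit of CHE lay inside the gene and that of GI 929 bp outside. Those of LUX and CCA1 were nearer to another gene, AT3G46630 and AT2G46820. With the nearest gene only the list fell to 2 genes (ratio 1.06) and for summits inside genes to 1 (0.73). In the lists drawn for auxin, 5 of 25 ARF, 3 of 32 Aux/IAA, 4 of 80 SAUR and 1 of 8 PIN genes were bound, at 1.32, 0.73, 0.56 and 0.84 times the expected number. Against genes within 1 Mb of similar length the ARF ratio was 0.92. For summits inside genes alone the PIN ratio was 1.44. ARF8 (AT5G37020) held a summit with a score of 163.6. The ARF list, matched by symbol, also took in ADP-ribosylation factors, among them the bound AT1G23490, so fewer than 5 auxin response factors were bound. The bound Aux/IAA entries included NPH4, an ARF gene matched by an alias. The adjusted p was 1 for ARF, Aux/IAA and PIN and 0.71 for SAUR (permutation).

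Among cell wall and growth genes, 4 of 37 expansins (ratio 0.90) and 5 of 33 XTH genes (1.21) were bound, with adjusted p of 1 for both (permutation). Neither direction held: with scores of 100 or more the expansin ratio was 2.47 (3 genes), and without chromosome 4 the XTH ratio was 0.81. The expansin genes EXPA6 (AT2G28950) and EXPA5 (AT3G29030) held summits with scores of 258.1 and 158.8. Cellulose synthase genes and their relatives were bound in 2 of 42 cases, 0.30 times the expected number (adjusted p = 0.28, permutation), and aquaporins in 6 of 53 (0.83, adjusted p = 1, permutation). The bound aquaporin entries included SIP1, matched by its symbol, and CAND1 and BRX, matched by an alias, which are not aquaporins. No JAZ gene of 12 was bound, against 1.57 expected (adjusted p = 0.76, permutation). Of the stress regulators, 8 of 35 ERF and DREB genes were bound (ratio 2.11, adjusted p = 0.28, permutation), led by ERF7 (AT3G20310, score 169.3), and 9 of 72 WRKY genes (0.93, adjusted p = 1, permutation), led by WRKY47 (AT4G01720, 243.6). The WRKY ratio was 1.59 (4 genes) with scores of 100 or more.

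The lists of abundant or inducible transcripts were bound at 1.57 to 1.98 times the expected number, none past the threshold. Light-harvesting and RBCS genes had 6 of 25 bound (adjusted p = 0.57, permutation), with RBCS3B (AT5G38410, score 223.8) and LHCB5 (AT4G10340, 124.4) at the top. Some members, such as the RBCS genes, have near-identical copies, so their reads can be placed at the wrong copy. Ribosomal protein genes had 13 of 59 bound (ratio 1.78, adjusted p = 0.28, permutation). Of these, RPS4 and RPS2 are disease resistance genes caught by the name pattern. Heat shock genes had 7 of 32 bound (ratio 1.57, adjusted p = 0.71, permutation). With the summits placed at random instead, the ribosomal protein list passed (ratio 2.47, adjusted p = 0.040, permutation). Random placement ignores that summits lay in genes more often than random positions. Its expected number was lower, 5.27 against 7.32 in matched lists, so this pass may partly restate that. With scores of 100 or more the heat shock ratio fell to 0.87 (1 gene), while that of light-harvesting and RBCS genes rose to 3.74 (3 genes), with adjusted p of 1 for both (permutation).

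**Figure D4:**
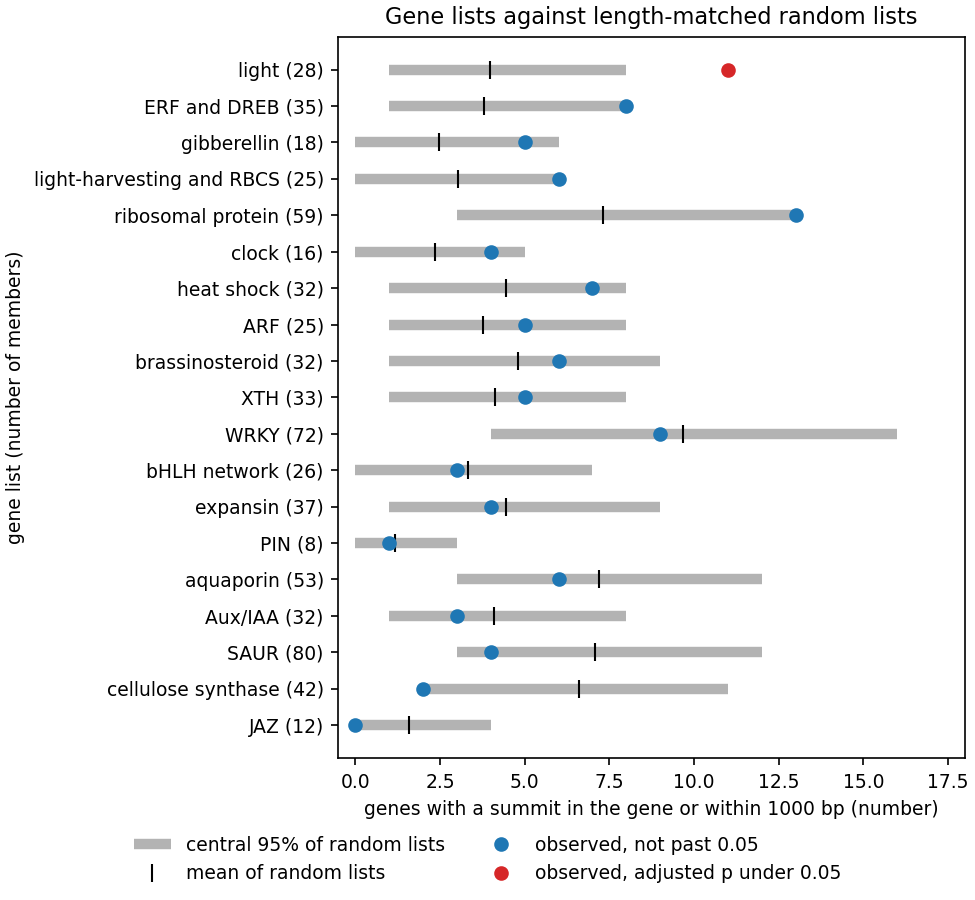
Number of genes with a summit inside or within 1000 bp in each of the 19 lists (points), with the mean (tick) and central 95% (grey bar) of 10000 random lists matched on gene length. Only the light list, with 11 genes against 3.98 expected, had an adjusted p under 0.05.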

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

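The list held 1 peak outside the nuclear chromosomes, which entered no comparison: on the mitochondrial sequence M, from 120757 to 121457 (TAIR9), with a score of 56.0 and a summit 32 fragments high, within the range of 14 to 100 of all summits (median 27). The control library's value at this place is not given in the list. No group held enough samples for a search for outlying samples.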

How the results depend on the processing

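The peak list fell from 2945 to 729 peaks at a score of 100 or more and to 1473 at or above the median score. Merging peaks within 500 bp left 2824. Bound protein-coding genes fell from 3499 to 927 and 1840 under these score limits and to 1934 for summits inside genes alone. The alternatives for genes bound, for the share inside genes and for the list tests that concern gene windows, neighbourhood or chromosome 4 were chosen after seeing the data. The share of summits inside genes (64.2% to 71.3%) and the low share in gene-poor windows (0.37 to 0.46 times the random share) stayed past the threshold in the same direction under each alternative run, and IBH1 kept its 1 peak. The number of lists past the threshold, 1, was 0 with scores of 100 or more, at or above the median score, for the gene alone and without chromosome 4, where 5 light genes with a summit were left out with the chromosome. It was 2 when summits were placed at random, which ignores their higher share inside genes, adding ribosomal protein genes. Under the 2 score limits, the ratio of the light list turned from 2.76 to 0.96 and 0.98, with fewer peaks by construction. Over its alternatives its adjusted p ranged from 0.0076, against genes within 1 Mb of similar length, to 1. Of 190 combinations of list and setting, 185 stayed on their side of the threshold, while 31 crossed a ratio of 1. Those were in the bHLH network, light, expansin, aquaporin, WRKY, heat shock, clock, brassinosteroid, PIN, ARF and XTH lists, so the direction of these lists is not settled. Of 101 bound list members, 29 stayed bound with scores of 100 or more and 99 with midpoints. Leaving out gene-poor windows gives no value for those windows themselves. The alternatives that need strand or sequence (windows upstream of a start, nearest start, all of those for the G-box and hexamers) were not run. No paired analysis was possible because each group is a single library. The depth of the libraries is unknown, so genes without a listed peak cannot be called free of IBH1.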

Other observations

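The strata, gene types and tests in this part were chosen after the data were seen, and of the tests of explanations only the shift of summits at tRNA genes was written down before its result.

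Genes close to the gene-poor regions held summits most often. Within 2 Mb of a gene-poor window there were 47.0 peaks per Mb (95% Poisson interval 44.1 to 50.03), and 1025 of 4369 protein-coding genes (23.5%) were bound. At 2 to 5 Mb there were 31.2 peaks per Mb and 15.1% of genes were bound. Beyond 5 Mb the values were 18.4 peaks per Mb (17.3 to 19.6) and 8.72% of 15816 genes. Inside the gene-poor windows there were 9.61 peaks per Mb, and 14.8% of 953 genes were bound, though 3.16% on chromosome 3. Of the 15 highest-scoring peaks, 11 lay within 2 Mb of a gene-poor window, including those at UBQ10, MYC2 and PHI-1. Of all 2944 nuclear peaks, 987 lay there. The 15 were picked by score, which was higher there at equal summit height, so their count is no separate support.

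Genes of tRNAs, which RNA polymerase III transcribes, and other noncoding genes also differed from random positions. Of 625 tRNA genes, 56 had a summit within 200 bp, against 7.48 when summits were moved at random within 20 kb (adjusted p = 0.0028, permutation). These gene types were tested with 1000 draws, and this value comes from the smallest p that they can give. The highest-scoring were at AT4G13265 (score 265.62) and AT5G56365 (256.58). For snRNA genes, which make spliceosomal RNAs, the count was 7 of 82, against 1.13, and for lncRNA genes 157 of 3480, against 87.4. Pseudogenes were below random, with 85 of 3917 against 154.7. Each of these 3 gene types had an adjusted p of 0.0028 (permutation), again from the smallest p possible, so these values do not rank the gene types. For miRNA genes, the count was 3 of 326 against 5.49, and for snoRNA genes 2 of 287 against 4.21 (adjusted p = 0.48 and 0.63, permutation). Protein-coding genes were above random as well, with 2388 of 27444 against 1869.7 (adjusted p = 0.0028, permutation). Overlap of lncRNA genes with protein-coding genes was not examined. The comparison at equal distance from protein-coding genes, given below, was run for tRNA and snRNA genes only. Whether the lncRNA excess is separate from that of protein-coding genes was therefore not tested.

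The higher density of bound genes beside gene-poor regions could follow from gene content, from peak calling, or from IBH1 itself. Gene content is argued against, since the share of bound genes within 2 Mb was at least 1.95 times that beyond 5 Mb on each of the 5 chromosomes, and 2.87 times overall at equal gene length. At equal summit height, log2 score was 0.21 higher near these regions than distally (permutation p = 0.0002, the smallest possible). The score weighs a peak against its background, so this difference nearly restates a lower local background there. It is no independent test of that explanation. Whether a lower background is the whole cause of the density cannot be told. Among peaks with summits of 34 fragments or more the ratio of peaks per gene was 3.41 (exact 95% interval 2.88 to 4.05). It was 3.92 among those of 22 fragments or fewer. Tall summits are still subject to the score threshold, which depends on the background: the summit near PHYB, 86 fragments high, scored only 62.0. Higher recovery of this chromatin in the tagged library and a true preference of IBH1 stay open, since the control's reads were not used here.

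Distance from protein-coding genes alone does not explain the summits at tRNA and snRNA genes: of as many windows at the same distance, 8.78 held a summit on average (at most 22 in 1000 draws), against 62 of the 636 genes that could be matched. Whether single summits belong to a neighbouring protein-coding gene stays open, since 9 of the 56 summits near tRNA genes lay inside one, and the bound set for a shift of all summits by 1000 bp was wrong: the shift left a mean of 7, close to the 7.48 of random moves, and any sharp summit would lose its place in this way whichever gene it belongs to. Summits near tRNA genes had a median score of 72.5 and a median height of 33 fragments, against 72.8 and 27 for other peaks. A candidate explanation is recovery of strongly transcribed loci whatever the tag, which predicts that abundant transcripts are bound often, but the pooled light-harvesting, ribosomal protein and heat shock lists, with summits at tRNA and snRNA genes and with RPS2 and RPS4 left out, were bound at 1.49 times the expected number (21 of 114 genes, permutation p = 0.078), against 1.66 times with RPS2 and RPS4 alone left out (24 of 114, permutation p = 0.016) and 1.76 times with all (26 of 116, permutation p = 0.0052). This decides nothing, as the pool was chosen after the lists' ratios were seen and no expression was measured, and signal in the control library and a role of IBH1 there stay open.

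The peak over IBH1 may come from DNA of the transgene itself, which adds copies of the gene to the tagged plants, or from binding of IBH1 to its own gene. With 81.0% of the peak inside the gene, its summit inside and 206 bp beyond the gene's bounds, these cannot be told apart: fragments extend past the ends of a cloned insert, and exons were not annotated here. Binding of IBH1 to its own gene was not tested separately.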
